A study of Danio rerio with 4 samples.

How the data were processed

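RNA from GFP-positive retinal cells of adult zebrafish was hybridised to 4 single-colour Agilent oligonucleotide arrays of design 015064, 1 array per sample. Per the labels, uninjured Muller glia were sorted from gfap:gfp fish (n = 2) and progenitors were sorted from fish of the 1016 tuba1a:gfp line 4 days after retinal injury (n = 2). Per the labels' protocols, 0.7 µg of RNA was labelled with a single dye for each array. The samples are described only as duplicates, so the labels leave open whether replicates are separate pools of fish or repeats of a single preparation. The files place all 4 arrays on 1 slide with 1 scan, so slide and scan do not separate the groups; the labels do not say whether sorting, RNA preparation or labelling did, and the spike-in signals differed between the groups. Whether the replicate numbers mark shared fish or days is not stated, and the comparison was fitted without them.

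The scanner files hold spot intensity on a linear scale, made by Feature Extraction 9.5.3.1 per the file headers, while the submitters' processing notes name version 9.1. The processed intensity used here was background-subtracted and detrended within each array by that software, per the file headers, with low values replaced by a surrogate value and nothing adjusted between arrays. A deposited table of values, also in units of intensity, was set against the scanner columns. There 100% of the 21495 values on each array equalled the background-subtracted signal of 1 of the probe's spots, within a relative tolerance of 0.001, so it is linear, not centred and not normalized between arrays. Its medians were 356 and 360 on the glia arrays and 467 and 488 on the progenitor arrays, with 1136, 914, 1578 and 1860 values below 0. The deposited intensities were converted to log2 here.

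The 1417 control spots and the spots that the software marked as outliers (11 and 23 on the glia arrays, 0 and 3 on the progenitor arrays) were left out, and saturated spots (3 or 4 per array) were kept. From each log2 signal the array's 75th percentile was subtracted, and the 2 spots of each probe were averaged. A probe was tested if it was well above background, by the software's own call, on both arrays of at least 1 group. This left 16596 of 21495 probes; of the 4899 not kept, 2 had been dropped for a missing value. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, residual plus prior degrees of freedom 3.92), with data.table (version 1.17.8) for input. P-values were adjusted by the Benjamini-Hochberg method over all probes kept, and the threshold was an adjusted p of 0.05. The probe with the highest mean over the 4 arrays stood for its gene; 95 of 1878 genes with several tested probes had probes called in opposite directions. Errors of log2 differences are standard errors from limma.

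Probes were named through their RefSeq accession in the GRCz12tu gene table (7323 probes), through a current symbol (598) or an older name (2352); 1639 kept the name in the file and 9583 had none. This gave 8753 named genes, 2339 of them with several probes. Coordinates are those in the scanner files, on danRer2, counted from 1. Where a gene was not well above background on either array of the dimmer group, its difference is given as a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

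Gene lists were tested with camera (limma, preset correlation between genes of 0.01), adjusted by Benjamini-Hochberg over 28 lists. Camera with an estimated correlation and fry were run beside it. With groups of 2, the estimated form rests only on the 2 residual degrees of freedom. Lens crystallins, ribosomal proteins, proteasome subunits, oxidative phosphorylation subunits, histones and splicing factors were collected by the start of the gene symbol alone. This also takes in other genes, among them rps6kal, a kinase, and psmc3ip, a recombination factor. On the splicing list lsm14aa and lsm14b stand by their symbols only.

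The comparison, its test, the 28 lists, the rule for naming genes and all alternatives except spike-in scaling were fixed before the data were examined. The rule names gfap and tuba1a, a set of regulators and markers whatever their values, the 10 largest changes in each direction among genes well above background on all 4 arrays, the 5 largest bounds in each direction, and up to 4 members of each list in each direction by adjusted p. The largest changes and bounds leave out probes with no gene name (7057 of those tested) and genes with placeholder symbols, such as zgc: or si: names. The pattern for clone names also leaves out every symbol that starts with fb to fj. After the alternatives had been run, the text was limited to 2 members per list and direction, with ube2c as a further lower mitosis gene. Genes of the lists written later, and tuba1b, were chosen after their values were seen.

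The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter on dim probes, a filter requiring signal on all arrays, outlier spots kept, a floor on low signals, an intensity trend in eBayes, the mean of a gene's probes, the deposited value table, the replicate number as a block, and leaving out each array in turn. A leave-one-out fit assumes that the lone array varies like the remaining group. Spike-in scaling was added after the spike-in signals were seen to differ between the groups.

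The steps were tested on simulated data with 16596 probes, 200 of them changed, 50 at each size. At 1.25-fold 0% were recovered, at 1.5-fold 32%, at 2-fold 74% and at 4-fold 94%, with 3 false calls among the unchanged probes. In the data 10872 of 16596 probes passed, so the adjusted threshold is less strict there and these recovery rates do not carry over. In the simulated list step on 7081 genes, 1 of 28 lists passed, the list that had been shifted by 0.5 on the log2 scale. This run does not test how camera behaves where the genes of a list vary together. In the data the estimated correlation ran from -0.07 for Jak-Stat genes to 0.22 for mitochondrial ribosomal proteins, the second above the preset value. The simulated result therefore does not carry over to the list calls. For arrays, the number of replicates limits the precision.

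A further 7 lists were written after the results were seen: surface epithelium, skeletal muscle, leukocyte-restricted genes, sterol biosynthesis, motile cilia, myelin and oligodendrocytes, and antigen processing and presentation. They were tested with camera and adjusted among themselves. For 2 of the lists, surface epithelium and leukocyte-restricted genes, the share of members that moved was set against 10000 random lists matched on brightness in 20 bins. As first written, that comparison had 2 outcomes, decided at the upper end of the middle 95% of the random lists. An undecided outcome was added only after the epithelium share was seen to equal that limit. RNA of tuba1a, apobec2a, apobec2b, hbegfa, her4.1, lin28aa, rho and rlbp1a is not analysed here, since no probe carries these names.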

Results

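Messenger RNA was measured on 4 single-colour oligonucleotide arrays, each hybridised with RNA from GFP-positive cells sorted from adult zebrafish retinas. Muller glia, the radial glial cells of the retina, came from uninjured gfap:gfp fish (n = 2 arrays, fish aged 7 months). Progenitors that arise from Muller glia after injury came from the 1016 tuba1a:gfp line, 4 days after the retina was poked with a 30-gauge needle (n = 2 arrays, fish aged 7 and 8 months). The 75th percentile signal was 4290 and 4464 on the glia arrays and 4816 and 4899 on the progenitor arrays, and 79.1%, 82.0%, 74.7% and 71.7% of spots were well above background. Across probes, log2 signals correlated at r = 0.999 between the 2 glia arrays and r = 0.998 between the 2 progenitor arrays, against 0.969 to 0.970 between groups. Replicate differences were only 1.27 and 1.46 times the noise between duplicate spots. The p-values therefore measure the spread between these arrays, which may be technical, since the samples are described only as duplicates.

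The comparison asks how gene expression in progenitors at 4 days after injury differs from that in Muller glia of the uninjured retina. Cell-cycle genes, regulators of reprogramming such as ascl1a, and leukocyte genes were higher in progenitors by camera, while photoreceptor and oxidative phosphorylation genes were lower, with medians that turned above 0 under spike-in scaling. With an estimated correlation 0 of these lists passed, the smallest adjusted p being 0.165. Of 7081 genes tested, 1955 were higher and 2851 lower in progenitors (limma, adjusted p below 0.05), 67.9% of all genes. Measured differences reached 2-fold for 548 higher and 283 lower genes and 8-fold for 90 and 45; with bounds in place of measured folds for dim genes, 548 and 224 reached 2-fold and 83 and 35 reached 8-fold. The 2-fold counts were 293 and 144 with normexp, 414 and 516 with median scaling, 521 and 181 with signal required on all arrays, and 2555 and 90 with spike-in scaling. The direction of small changes depended on how arrays were scaled: 40.7% of changed genes were higher, against 23.3% when each array was scaled on its median. When arrays were scaled on their spike-in controls, which were dimmer on the progenitor arrays (median signals 2923 and 3070, against 5444 and 6145), 97.1% were higher. Median scaling shifted the median of all genes by -0.22 and spike-in scaling by 0.95 on the log2 scale. All differences are relative to the 75th percentile of each array, where the median gene stood at -0.11. With normexp background correction 824 genes were higher and 1146 lower. The GFP line and the injury both differ between the groups, so neither can be separated from the other.

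Among the genes fixed for naming, the proneural factor ascl1a and the protease mmp9 rose most. The ascl1a signal (danRer2 chromosome 4, 17876001 to 17876060, minus strand) rose 39.8-fold, from -2.64 ± 0.10 to 2.68 ± 0.01 (SD, n = 2) on the scaled log2 axis (limma, adjusted p = 5.6e-05). The mmp9 signal (chromosome 8, 18880349 to 18880408, plus strand) rose 34.8-fold, by 5.12 ± 0.06. The transcriptional repressor insm1a rose by 2.52 ± 0.05, sox2 by 1.00 ± 0.04, pcna by 0.98 ± 0.05 and tgif1 by 0.63 ± 0.06 on the log2 scale, although the other tgif1 probe stood at -0.22. The Wnt antagonist dkk1b was 4.29-fold lower (-2.10 ± 0.04).

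Of the transgene promoters' own genes, gfap (chromosome 3, 25108411 to 25108470, plus strand) was 1.61-fold higher in progenitors (0.69 ± 0.05, limma, adjusted p = 0.00132), with its 4 probes between 0.24 and 0.76. No probe was named tuba1a, and the related tuba1b, chosen after its value was seen, was higher by 1.19 ± 0.04. The glutamine synthetase gene glula did not pass (-0.12 ± 0.04, adjusted p = 0.07), but passed with median scaling at -0.35 and with an intensity trend, and stood at 0.01 with quantile normalization. Increases of stat3 (1.21 ± 0.28), mdka (0.29 ± 0.07) and six3b (0.22 ± 0.05) passed narrowly. The stat3 call was lost without either progenitor array (1.25 and 1.17), without the filter on dim probes, and with normexp (0.46). The mdka and six3b calls were lost without glia replicate 1 (0.34 and 0.23), glia replicate 2 (0.24 and 0.22) or progenitor replicate 1 (0.23 and 0.18). Both were also lost with normexp, without the filter on dim probes and with median scaling (0.07 and 0.00). For mdka the mean of its 2 probes was -0.15, and the call was lost with the deposited value table.

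**Figure D1:**
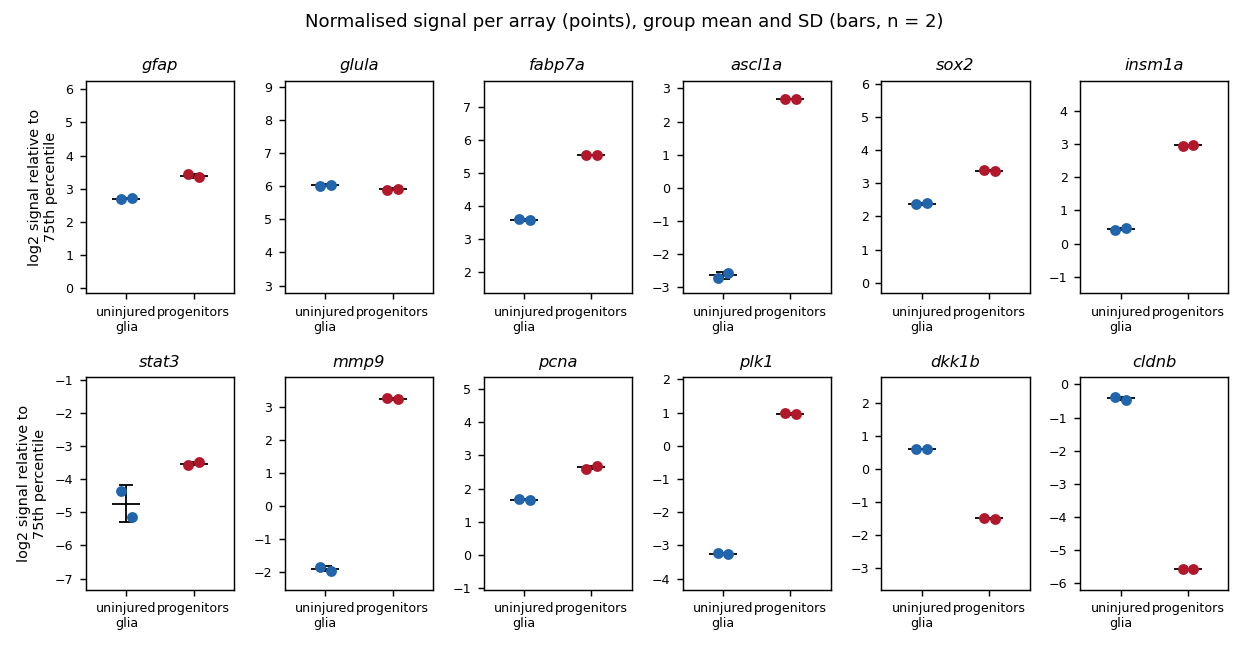
Scaled log2 signal (array 75th percentile set to 0) of 12 named genes in uninjured Muller glia and in progenitors at 4 days post injury, with a point for each array and the mean ± SD (n = 2). The progenitor mean of ascl1a lies 5.31 above and that of dkk1b lies at -2.10 relative to the glia mean, with spike-in scaling adding 0.95 to every difference and turning glula to 0.82.

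Genes of DNA replication and mitosis rose as a group. Of 39 replication genes 34 were higher and 2 lower, with a median of 1.45 (camera, adjusted p = 1.5e-12, adjusted p = 0.165 with an estimated correlation). The helicase subunits mcm4 and mcm3 rose by 3.53 ± 0.05 and 3.22 ± 0.05. Of 37 mitosis genes 31 were higher and 3 lower, with a median of 2.99 (camera, adjusted p = 9.8e-13, adjusted p = 0.165 with an estimated correlation), led by the kinases plk1 (4.22 ± 0.04, 18.6-fold) and cdk1 (4.02 ± 0.04). Counts adjusted over the list alone were the same for both lists. The 5 decreases in these lists depended on the processing. For mki67 the brightest probe gave -0.42 and the other 3.46, and the mean of the probes was 1.52. Neither tpx2 nor rbl1 was well above background in progenitors, and neither had a bound above 1. The tpx2 difference turned to 0.51 without glia replicate 1 and to 0.62 without progenitor replicate 2, and to 0.69 without the filter on dim probes. The rbl1 call was lost without either progenitor array (-0.92 and -0.88). The tk1 call (-0.52 ± 0.10) was lost without either glia array (-0.50 and -0.55). The ubiquitin-conjugating enzyme gene ube2c, at least 1.28-fold lower and dim in progenitors, lost its call without glia replicate 2 (-0.53). All 5 calls were lost with normexp, and mki67, tk1, ube2c and rbl1 stood at 0.52, 0.42, 0.37 and 0.04 with spike-in scaling. Among 9 histone genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.104), although it did with normexp (0.0382) and with the mean of probes (0.0301). It included h2ax, 2.29-fold higher, and histh1l1 at -0.67 ± 0.04.

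Regulators of reprogramming and progenitors were higher as a group, with 25 of 39 higher and 10 lower (25 and 11 adjusted over the list alone) and a median of 0.45 (camera, adjusted p = 0.00171, adjusted p = 0.193 with an estimated correlation). Decreases were led by meis1b (-0.58 ± 0.05) and six7 (-0.80 ± 0.06), which stood at 0.36 and 0.15 with spike-in scaling. The gene six7 is also on the list of cone photoreceptor markers, which was lower as a group. Muller glia markers were also higher rather than lower: 11 of 20 rose and 4 fell, adjusted over the list alone as well, with a median of 0.30 (camera, adjusted p = 0.0203, adjusted p = 0.201 with an estimated correlation). This call ended with spike-in scaling (adjusted p = 0.785). The fatty acid binding protein gene fabp7a rose by 1.95 ± 0.04 and her6 2.15-fold, while ptgdsb.1 (-1.08 ± 0.04) and the connexin gene gja1b (-0.55 ± 0.04) were lower, gja1b turning to 0.39 with spike-in scaling.

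Signalling lists were mixed. In the Jak-Stat and gp130 list 5 of 12 genes were higher and 4 lower, adjusted over the list alone as well, and the list did not pass (median -0.03, but ranked higher by camera, adjusted p = 0.281). Its largest increases were the cytokine receptor-like gene crlf1a (4.51 ± 0.05, with its other probe at 2.43) and the feedback inhibitor socs3b (3.18 ± 0.04). Lower members were socs1a (-0.90 ± 0.06) and stat1b (-0.39 ± 0.04), the second lost with normexp. In the Notch list 12 of 26 genes were higher and 4 lower, adjusted over the list alone as well (camera, adjusted p = 0.0108, adjusted p = 0.271 with an estimated correlation). Its median of 0.14 turned to -0.08 with median scaling, and the call ended with spike-in scaling (adjusted p = 0.114). The ligand genes dlb and dlc rose by 3.54 ± 0.08 and 2.47 ± 0.06, dlc losing its call with normexp (1.60), while dld (-0.37 ± 0.04) and her8a (-0.64 ± 0.06, lost with normexp) were lower, at 0.58 and 0.31 with spike-in scaling.

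The Wnt list had 13 higher and 14 lower genes of 35, with a median of -0.13 that turned to 0.81 with spike-in scaling (camera, adjusted p = 0.829). The secreted inhibitor gene sfrp1a rose by 1.68 ± 0.04 and dvl2 by 1.12 ± 0.05, while wif1 was lower (-0.86 ± 0.04, and 0.09 with spike-in scaling). With normexp sfrp1a turned to -0.13 and dvl2 lost its call. The TGF-beta and BMP list had 13 higher and 16 lower genes of 39, with a median of -0.08 that turned to 0.86 with spike-in scaling (camera, adjusted p = 0.786). There smad5 (0.85 ± 0.04) and smad9 (0.91 ± 0.06) were higher, and acvr2ba (-0.98 ± 0.04) and bmp5 (-0.82 ± 0.05) lower, the calls of smad9 and bmp5 ending with normexp. Counts in both lists were the same adjusted over the list alone. In the DNA methylation list 7 of 13 genes were higher and 1 lower, adjusted over the list alone as well, with a median of 0.29 (camera, adjusted p = 0.00956, adjusted p = 0.287 with an estimated correlation). Spike-in scaling ended this call (adjusted p = 0.114). The stress-response genes gadd45bb and gadd45gb.1 rose by 2.96 ± 0.08 and 1.92 ± 0.07, and the only lower member was mbd2 (-0.66 ± 0.06, and 0.29 with spike-in scaling).

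Matrix, stress and cytoskeletal genes rose. Extracellular matrix and protease genes had 22 of 29 higher and 3 lower, with a median of 0.59 (camera, adjusted p = 2.0e-06, adjusted p = 0.165 with an estimated correlation), a call that ended with spike-in scaling (adjusted p = 0.398). After mmp9, the collagen chaperone gene serpinh1b was among the highest (3.37 ± 0.04), although its call was lost with normexp (1.91). By contrast postnb was 11.4-fold lower (-3.50 ± 0.04) and the proteoglycan gene lum was lower by -1.26 ± 0.06. Immediate early and stress genes had 26 of 34 higher and 4 lower, with a median of 0.61 (camera, adjusted p = 1.9e-06, adjusted p = 0.168 with an estimated correlation). The transcription factor genes atf3 (3.37 ± 0.04) and egr2b (2.02 ± 0.05) were among the higher members, while dusp1 (-0.61 ± 0.05) and dusp6 (-0.58 ± 0.04) were lower, at 0.34 and 0.36 with spike-in scaling. Tubulins and growth-associated cytoskeletal genes had 12 of 20 higher and 3 lower, with a median of 0.35 (camera, adjusted p = 0.00196, adjusted p = 0.193 with an estimated correlation). There tmsb rose by 4.30 ± 0.04 and gap43 by 3.09 ± 0.05, against stmn4 (-0.74 ± 0.05) and tmsb1 (-0.71 ± 0.05), which stood at 0.20 and 0.23 with spike-in scaling. Counts in these lists were the same adjusted over the list alone.

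The changes and bounds in this paragraph are the largest among genes that the naming rule allows, which leaves out placeholder symbols. The largest increases among such genes measured on all arrays were, after ascl1a and mmp9, s100a1 (4.69 ± 0.27), trip13 (4.61 ± 0.05), crlf1a, ropn1l (4.49 ± 0.16), f5 (4.31 ± 0.06), tmsb, rrm2l (4.23 ± 0.05) and plk1. With normexp the calls of s100a1 and ropn1l were lost (1.93 and 2.23). The largest decreases included tacstd (-5.71 ± 0.06, 52.4-fold), the claudin genes cldni (-5.32 ± 0.04), cldnb (-5.14 ± 0.05) and cldna (-4.52 ± 0.08), and the keratin gene cyt1 (-4.05 ± 0.06, its other probe -0.40). They also included mala.2 (-5.46 ± 0.04), foxq1b (-5.02 ± 0.05), mid1ip1a (-4.67 ± 0.05), tnn (-4.30 ± 0.06) and gpx4b (-4.05 ± 0.05). Genes not well above background in glia included dbx1a, at least 17.7-fold higher in progenitors, haus4 (at least 13.8-fold), mybl2b (10.2), rbp2a (9.07) and lin28ab (7.70). All 5 calls were lost with normexp, with differences from 0.32 for lin28ab to 1.25 for dbx1a. Genes not well above background in progenitors included tmem30b, at least 18.9-fold lower, dhrs13a.2 (14.1), dmrta2 (11.3), upk1a (8.50) and esrp2 (6.48, its call lost with normexp). In all, 18 higher genes were dim in glia and 235 lower genes were dim in progenitors, 60 of these without a bound above 1.

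Markers of other retinal and blood cells moved in different directions. Microglia and leukocyte markers were higher, 24 of 27 with 1 lower (25 and 1 adjusted over the list alone) and a median of 1.49 (camera, adjusted p = 1.5e-11, adjusted p = 0.165 with an estimated correlation). The cytokine gene il1b rose by 3.46 ± 0.04 and the complement gene c1qb by 2.92 ± 0.05. The lower member was cybb (-0.31 ± 0.06), lost without either glia array (-0.29 and -0.32) and with normexp, and at 0.64 with spike-in scaling. Erythrocyte markers were lower, 11 of 14 with 0 higher, adjusted over the list alone as well, and a median of -1.39 (camera, adjusted p = 0.00251, adjusted p = 0.193 with an estimated correlation), including nt5c2l1 (-2.21 ± 0.04) and epb41b (-1.97 ± 0.04). With bounds for dim genes the median was -1.07.

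Photoreceptor and neuronal markers were lower relative to the 75th percentile. Rod markers had 15 of 17 lower and 1 higher, adjusted over the list alone as well, and their median of -0.40 turned to 0.55 with spike-in scaling (camera, adjusted p = 0.00176, adjusted p = 0.193 with an estimated correlation). They included abca4a (-1.52 ± 0.06) and prph2b (-1.10 ± 0.04). The higher rod gene nr2e3 (0.34 ± 0.06) lost its call with normexp, with median scaling (0.12) and without glia replicate 1 (0.32). Cone markers had 19 of 23 lower and 0 higher (20 lower adjusted over the list alone), with a median of -0.72 that turned to 0.23 with spike-in scaling (camera, adjusted p = 1.4e-05, adjusted p = 0.193 with an estimated correlation). The cone opsin genes opn1mw3 and opn1lw2 stood at -1.93 ± 0.04 and -1.62 ± 0.04. On the scaled log2 axis opn1lw2 was bright in both groups, at 4.55 in glia and 2.93 in progenitors. A change in the cell mixture was therefore not separated from expression in the sorted cells. Inner retinal neuron and synapse markers had 21 of 29 lower and 3 higher (22 and 3 adjusted over the list alone), with a median of -0.45 that turned to 0.49 with spike-in scaling (camera, adjusted p = 0.00929, adjusted p = 0.201 with an estimated correlation). That scaling also ended the call (adjusted p = 0.390). Lower members included nsfa (-0.82 ± 0.04, and 0.13 with spike-in scaling) and calb2b (-0.66 ± 0.04, and 0.29), and higher members isl2b (0.75 ± 0.06) and prkcbb (0.74 ± 0.07, lost with normexp).

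The remaining cell-type lists did not pass. Vascular and perivascular markers had 7 of 14 higher and 5 lower, with a median of 0.13 that turned to -0.09 with median scaling and to -0.06 with normexp (camera, adjusted p = 0.275). There cldn5a (1.90 ± 0.06) and cldn5b (1.67 ± 0.04) were higher, while acta2 (-2.02 ± 0.09) and flt4 (-1.16 ± 0.06) were lower, cldn5a and flt4 losing their calls with normexp. Retinal pigment epithelium and pigment cell markers had 2 of 10 higher and 4 lower, with a median of -0.10 that turned to 0.84 with spike-in scaling (camera, adjusted p = 0.850). They included dct (0.42 ± 0.04) and gpr143 (-0.64 ± 0.04, and 0.31 with spike-in scaling). Lens crystallins had 8 of 13 lower and 1 higher, with a median of -0.52 (-0.41 with bounds for dim genes) that turned to 0.43 with spike-in scaling (camera, adjusted p = 0.0501). The list passed as lower without glia replicate 1 (median -0.71), with the mean of probes and with spike-in scaling. With spike-in scaling it was lower only relative to the other genes, since the median of all genes stood at 0.83. The lower cryaba (-1.16 ± 0.09) lost its call with normexp. Counts in these lists were the same adjusted over the list alone.

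Translation and energy metabolism genes moved apart. Cytosolic ribosomal protein genes had 66 of 70 higher and 3 lower (67 and 3 adjusted over the list alone), with a median of 0.62 (camera, adjusted p = 4.4e-17, adjusted p = 0.193 with an estimated correlation). They included rpl36a (1.18 ± 0.05). Lower were rpl10 (-0.50 ± 0.06), rps19 (at least 1.18-fold, dim in progenitors) and the kinase gene rps6kal (-0.41 ± 0.05), which stood at 0.44, 0.37 and 0.54 with spike-in scaling and all lost their calls with normexp. Ribosome biogenesis genes had 26 of 39 higher and 1 lower (27 and 1 adjusted over the list alone), with a median of 0.28 (camera, adjusted p = 1.0e-05, adjusted p = 0.193 with an estimated correlation), including nop16 (1.17 ± 0.05) and npm1a (2.14-fold). With median scaling 12 were higher and 9 lower (median 0.06), and the list still passed (adjusted p = 5.9e-04). Oxidative phosphorylation subunits had 41 of 45 lower and 1 higher (42 and 1 adjusted over the list alone), with a median of -0.39 that turned to 0.56 with spike-in scaling (camera, adjusted p = 3.9e-07, adjusted p = 0.165 with an estimated correlation). That scaling ended the call (adjusted p = 0.471). Lower members included cox6a2 (-1.18 ± 0.05) and atp5pf (-0.98 ± 0.05), and the higher member was cox6b1 (0.42 ± 0.06), lost with normexp and with median scaling (0.19).

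Glycolysis genes were lower as well, 22 of 26 with 3 higher, adjusted over the list alone as well, and their median of -0.46 turned to 0.48 with spike-in scaling (camera, adjusted p = 0.00251, adjusted p = 0.227 with an estimated correlation). That scaling ended the call (adjusted p = 0.614). Rod and cone markers were lower too (medians -0.40 and -0.72). Members tpi1a (-0.88 ± 0.05) and ldhbb (-0.79 ± 0.04) were lower, at 0.07 and 0.16 with spike-in scaling. The hexokinase gene hk2 (1.23 ± 0.06, lost with normexp) and aldoab (1.04 ± 0.05) were higher. Mitochondrial ribosomal protein genes had 16 of 27 lower and 1 higher, adjusted over the list alone as well, with a median of -0.22 that turned to 0.73 with spike-in scaling (camera, adjusted p = 0.0281, adjusted p = 0.487 with an estimated correlation). The call was lost with quantile normalization (adjusted p = 0.0872), with spike-in scaling (0.471), and without glia replicate 1 (0.0539), glia replicate 2 (0.0534) or progenitor replicate 2 (0.0507). It included mrpl43 (-0.84 ± 0.05) and mrps34 (-0.44 ± 0.04), at 0.11 and 0.51 with spike-in scaling. Proteasome genes had 19 of 37 higher and 1 lower (18 and 1 adjusted over the list alone), with a median of 0.17 that turned to -0.05 with median scaling (camera, adjusted p = 3.4e-04, adjusted p = 0.193 with an estimated correlation). Median scaling ended the call (adjusted p = 0.0535), with 7 higher and 11 lower. The immunoproteasome-related genes psmb9a (2.03 ± 0.11, lost with normexp) and psmb12 (1.27 ± 0.05) were among the highest. RNA splicing factors had 17 of 56 higher and 11 lower (16 and 10 adjusted over the list alone), with a median of -0.02 that turned to 0.09 with quantile normalization (camera, adjusted p = 0.275). The list passed as higher with quantile normalization (adjusted p = 0.00831), normexp (0.0274) and spike-in scaling (0.0362), whereas median scaling gave 6 higher and 32 lower (median -0.24, adjusted p = 0.982). It included snrpf (0.86 ± 0.05) and prpf31 (-0.71 ± 0.04, and 0.24 with spike-in scaling).

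By camera, 13 lists were higher, 7 lower and 8 not past the threshold. By fry, which asks only whether a list's genes move on balance in a direction, 16 were higher and 10 lower. Jak-Stat, Wnt, TGF-beta and splicing lists had medians below 0 but were ranked higher by camera.

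**Figure D2:**
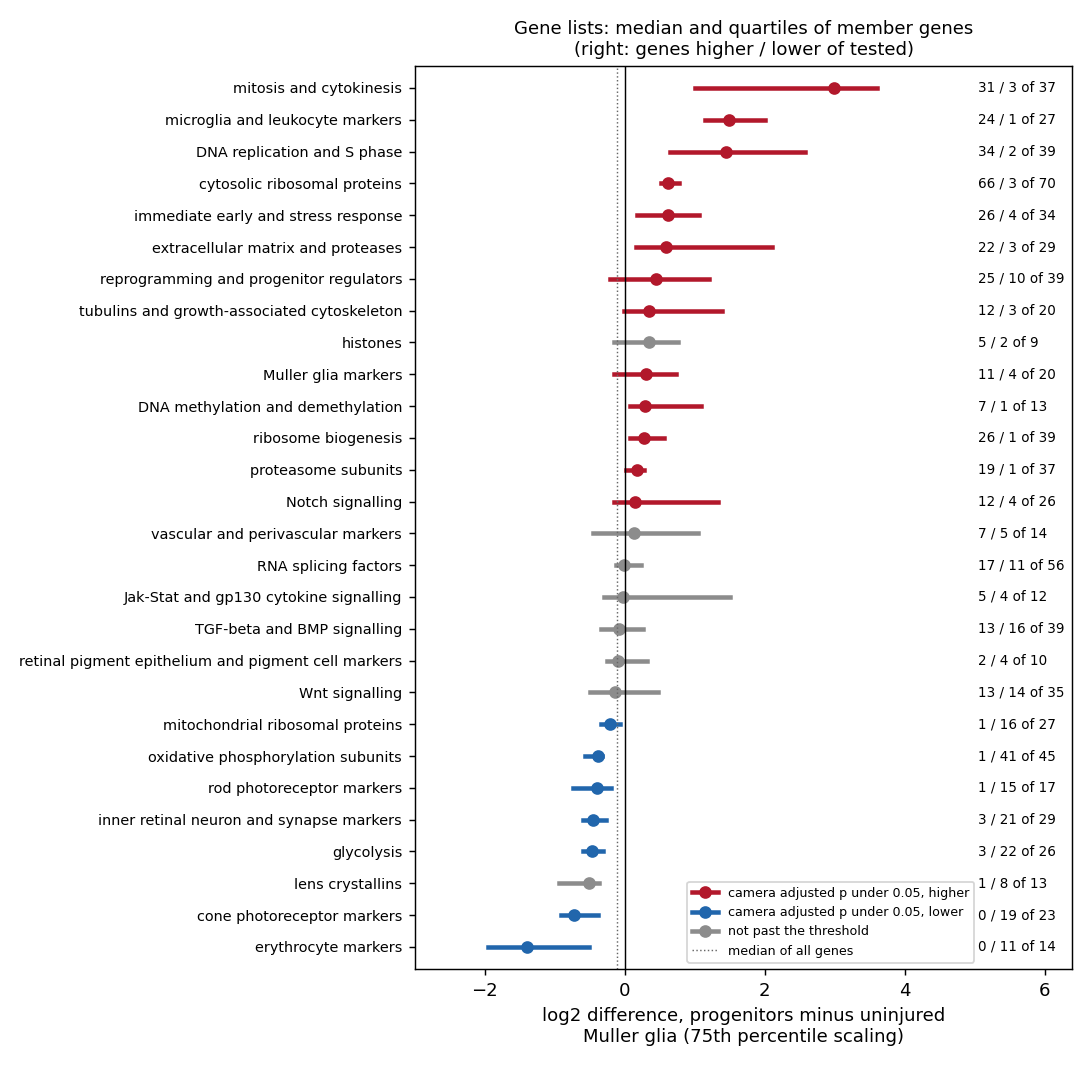
Log2 difference (progenitors minus uninjured Muller glia, n = 2 arrays each, scaled on the 75th percentile) of the genes in each of the 28 lists, with points for medians, bars for quartiles, and counts of higher and lower genes at the right. Medians run from -1.39 for erythrocyte markers (-1.07 with bounds for dim genes) to 2.99 for mitosis genes (2.97 with bounds), with spike-in scaling adding 0.95 to every value and so turning all negative medians except the erythrocyte one, and median scaling turning the Notch, vascular and proteasome medians below 0.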

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

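Spike-in scaling was chosen after the data were seen; the other alternatives were planned. Over the 165 genes in the text and all alternatives, 2455 of 2624 comparisons kept direction and side of the threshold, 111 lost the call, 2 gained one and 56 reversed. Over all 239 genes that the naming rule and the later choices take in, 3539 of 3806 kept both, 179 lost the call and 86 reversed, 18 of these without spike-in scaling; the text was limited to fewer genes after these were seen. For gene lists, 555 of 623 comparisons kept both, 42 lost the call, 14 gained one and 12 reversed. Of the 831 main calls of at least 2-fold, 460 were also called in the same direction with normexp and between 701 and 831 in the other alternatives chosen beforehand; spike-in scaling gave 740. Except where stated, the cause was not tested.

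With normexp, 824 genes were higher and 1146 lower, 293 and 144 of them at least 2-fold, and replicate arrays correlated at 0.996. Median scaling gave 1296 higher genes and 516 lower at least 2-fold. The filter requiring signal on all arrays, which by construction tests fewer dim genes, gave 181 lower at least 2-fold and a correlation of 0.99889. The correlation was 0.99695 without the filter and 0.99766 with the value table, against 0.99846. With an estimated correlation, which rests on 2 residual degrees of freedom, 0 lists were higher and 0 lower by camera, where fry called 16 and 10. Spike-in scaling, which by construction adds 0.95 to every difference, gave 6337 higher and 192 lower genes, 2555 and 90 of them at least 2-fold, and 4 lower lists. The constant leaves the gap between a list's median and that of all genes unchanged. Camera works on moderated t values, to which the constant adds most where errors are small, so its calls can change without that gap.

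The replicate numbers are not shown to pair the samples: over 2 pairs, deviations correlated at 0.0585. With the number as a block, 1801 genes were higher and 2607 lower. Of the results in the text this block ended the calls of mrps15 and psmd6, brought lens crystallins past the threshold (adjusted p = 0.0171) and changed no other call. Leaving out each array gave 1547 to 1654 higher and 1976 to 2328 lower genes.

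Reversals with normexp were crygn1 (-0.26), rgrb (-0.12), sfrp1a (-0.13) and the test of the skeletal muscle list, whose median stayed below 0 (-0.39, adjusted p = 0.610). With quantile normalization they were glula (0.0129) and the TGF-beta (-0.13) and skeletal muscle (-0.0402) lists, whose test changed direction while the medians stayed below 0. Median scaling turned mrps15 to -0.0511. Without the filter tpx2 stood at 0.69 and the test of the Wnt list (-0.22) changed direction. The floor on low signals turned cryabb (0.33), rbl1 (0.0303) and tpx2 (0.0417), and the value table turned the same genes (0.25, 0.0579 and 0.35), all dim in progenitors. The mean of probes turned h3f3c (0.14), mdka (-0.15) and mki67 (1.52), whose probes disagree, and the test of the skeletal muscle list, with its median unchanged (-0.19, adjusted p = 0.885). With fry the TGF-beta list (-0.0807) was lower. Leaving out each array, tpx2 ranged from -1.12 to 0.62 and the skeletal muscle median from -0.31 to -0.0240, its test changing direction without progenitor replicate 1 (-0.23).

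With spike-in scaling the test of the Wnt (0.81), pigment epithelium (0.84), vascular (1.08), mitochondrial ribosomal protein (0.73) and skeletal muscle (0.75) lists changed direction. The added constant turned bmp5 (0.13), calb2b (0.29), cryabb (0.00913), cybb (0.64), dld (0.58), dusp1 (0.34), dusp6 (0.36), foxj1a (0.25), gja1b (0.39), glula (0.82), gpr143 (0.31), h3f3c (0.66) and her8a (0.31). It also turned histh1l1 (0.27), ldhbb (0.16), lsm14b (0.32), mbd2 (0.29), meis1b (0.36), mki67 (0.52), mrpl43 (0.11), mrps34 (0.51), nsfa (0.13), prpf31 (0.24), psmd6 (0.76), rbl1 (0.0415), rcl1 (0.65) and rpe65a (0.60). The others were rpl10 (0.44), rps19 (0.37), rps6kal (0.54), six7 (0.15), socs1a (0.0427), stat1b (0.55), stmn4 (0.20), tk1 (0.42), tmsb1 (0.23), tpi1a (0.0696), ube2c (0.37) and wif1 (0.0898). In the main analysis 235 lower genes were not well above background on either progenitor array.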

Other observations

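The 7 lists in this part were written after the results were seen, prompted by genes seen there, so their p-values are not independent evidence, and all tests below were also chosen then except those of brightness and of the gap under other scalings. Genes of sterol biosynthesis were lower in progenitors, 13 of 18 with 1 higher and a median of -0.75 (camera adjusted over these 7 lists, adjusted p = 8.4e-04, adjusted p = 0.174 with an estimated correlation). The median stood at 0.20 with spike-in scaling, still below the shift of all genes. The enzymes of the pathway msmo1 and cyp51 stood at -2.04 ± 0.05 and -2.04 ± 0.05, hmgcs1 at -1.82 ± 0.05 and sc5d at -1.80 ± 0.05, while lbr was higher (0.55 ± 0.04). Motile cilia genes were higher, 16 of 24 with 5 lower and a median of 1.29 (camera, adjusted p = 8.4e-04, adjusted p = 0.107 with an estimated correlation). They included drc2 (3.19 ± 0.06), odad1 (2.53 ± 0.15), dnaaf4 (2.48 ± 0.14) and spag6 (2.17 ± 0.06), all of which lost their calls with normexp, as did the list (median 0.21, 0 higher and 1 lower, adjusted p = 0.234). The call also ended with spike-in scaling (adjusted p = 0.248). The regulator gene foxj1a was lower (-0.70 ± 0.06, and 0.25 with spike-in scaling), as was dnal4a (-1.16 ± 0.10, lost with normexp).

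Myelin and oligodendrocyte genes were lower, 10 of 11, with a median of -0.77 that turned to 0.18 with spike-in scaling (camera, adjusted p = 0.010, adjusted p = 0.154 with an estimated correlation). Median scaling ended that call (adjusted p = 0.0555). They included cd9b (-1.60 ± 0.04), mbp (-1.42 ± 0.10) and plp1b (-1.08 ± 0.05), and the exception was olig2, higher by 1.66 ± 0.07. Antigen processing and presentation genes were higher, 14 of 16 with 1 lower and a median of 1.303 (camera, adjusted p = 1.5e-05, adjusted p = 0.104 with an estimated correlation), and 6 of them also stand on the fixed lists. Spike-in scaling ended the call (adjusted p = 0.176). Leukocyte-restricted genes were higher by a similar median (1.49), and the sources of the increases were not separated. They included psmb8a (2.52 ± 0.22, lost with normexp), ifi30a (2.44 ± 0.06) and ctss1 (1.99 ± 0.04), and the lower member was mhc1uea (-1.72 ± 0.04). Surface epithelium genes were lower in progenitors, that is, higher in the uninjured glia arrays: 31 of 42 lower and 7 higher, median -2.93, -1.99 with spike-in scaling (camera, adjusted p = 4.7e-05, adjusted p = 0.104 with an estimated correlation). The keratin gene krt5 stood at -4.02 ± 0.05, cdh1 at -3.91 ± 0.08 and krt4 at -1.91 ± 0.05, but krt8 and krt18b were higher by 1.69 ± 0.04 and 2.39 ± 0.05. Skeletal muscle genes did not pass, with 8 of 21 higher and 8 lower (median -0.19, camera, adjusted p = 0.912).

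For the lower surface epithelium genes, a lower sorted share raising every other cell type alike was set against the leukocyte and rod medians of the fixed lists. These lay 1.88 apart (95% interval 1.63 to 2.40, resampling genes). Both medians were already seen, so they show only that not all other cell types moved alike. Rod, cone, inner retinal neuron and erythrocyte medians were below 0 (-0.40, -0.72, -0.45 and -1.39). A lower sorted share in the uninjured samples that raises these types but not leukocytes therefore stays open. The surface epithelium list was prompted by 17 members already seen, all of them lower, and its median rests on these. Among the other 25, 14 were lower and 7 higher, with a median of -0.64, below the middle 95% of brightness-matched random lists (-0.32 to 0.16). Dim signal stays open for the list as a whole. It is argued against only for members bright in both groups. Of those already seen, krt5 stood at 3.87 in glia and -0.15 in progenitors on the scaled log2 axis, and krt91 at 3.41 and -0.53. The 36 members above background on all arrays had a median of -2.27, but this rests in part on 14 members already seen, all of them lower (median -4.04). The 22 above background on all arrays that were not seen before go both ways, 11 lower and 7 higher (median -0.13, 95% interval -1.42 to 0.72), and decide nothing. Epithelial cells or their RNA in the uninjured samples may be the source. Sorting on GFP should remove such cells, but the cone gene guca1c was bright in both groups. It stood at 5.96 in glia and 4.87 in progenitors on the scaled log2 axis, so removal of other cells' RNA cannot be assumed. Of the 25 members not seen before 56% were lower, equal to the upper end of the middle 95% of brightness-matched random lists (median 40%). This tie counted against the explanation under the rule as first written. It is read here as undecided, an outcome added after the value was seen. A difference between the GFP lines stays open, untested.

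Leukocyte-restricted genes, all 19 of them also on the fixed leukocyte list, were higher in progenitors: 16 higher and 1 lower (17 and 1 adjusted over the list alone), median 1.49 (camera, adjusted p = 7.9e-08, adjusted p = 0.104 with an estimated correlation). They included spi1b (2.30 ± 0.05), mpeg1.1 (1.78 ± 0.06), lcp1 (1.75 ± 0.04) and rac2 (1.49 ± 0.05). The lower member was cybb, and csf1ra (0.32 ± 0.10) and aif1l (-0.06 ± 0.05) did not pass when adjusted over all probes. Brightness is argued against, since the fixed list's median lay at percentile 100 of random lists (95% of which lay between -0.24 and 0.18). The rod median lay -1.88 from the leukocyte median (95% interval -2.40 to -1.63, resampling genes). Both medians were already seen, so they show only that the cell types did not all move alike. A lower sorted share that raises leukocytes more than other types stays open. Leukocytes or their RNA in the progenitor samples may be the source. Sorting on GFP should remove such cells, but this cannot be assumed, since the cone gene guca1c stood at 4.87 in progenitors on the scaled log2 axis. Of the restricted members 84.2% were higher (random median 31.6%). The counts of the fixed list, already seen, allowed no fewer than 16 of the 19, so the test decides nothing. Leukocytes as the source and expression of these genes by the progenitors after injury cannot be told apart, because the restricted genes are a part of the list that showed the pattern.

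Cytosolic ribosomal protein genes were higher and oxidative phosphorylation genes lower, with medians 1.00 apart, and scaling is argued against for this gap, which was 0.974 with quantile normalization, while median and spike-in scaling add a constant and cannot change it. For the direction of the oxidative phosphorylation genes scaling stays open, since spike-in scaling turned their median to 0.557 and ended the call (adjusted p = 0.471), and which scaling is right is not known. Brightness is argued against for both lists, whose medians lay at percentiles 100 and 0.03 of matched random lists (95% of which lay between -0.34 and -0.20, and between -0.30 and -0.05). Fewer photoreceptors in the progenitor samples stay open as a source of the lower oxidative phosphorylation genes. Under this explanation their median should fall by less than the rod median, and a larger fall would count against it. The medians differed by only 0.00776 (95% interval -0.22 to 0.34, resampling genes). The prediction was therefore not met, and the comparison decides nothing, since the interval includes differences in both directions. The cone median lay lower, at -0.72, and was not compared by an interval. The explanations cannot be told apart, because a lower oxidative phosphorylation median would also arise if the progenitors themselves expressed less with injury or proliferation, which was not tested.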
